A study of Mus musculus with 6 samples.

How the data were processed

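RNA of M2-like macrophages of C57BL/6 mice aged 10 weeks was measured on 6 Illumina mouse bead arrays, 2 each for the intact heart, the infarcted heart and the peritoneal cavity. Per the labels, total RNA was extracted with Trizol, cleaned up and treated with DNase I, and biotinylated cRNA was prepared with the Ambion MessageAmp kit. Per the file headers, the deposited table holds for each array a signal intensity and a detection p-value for each of 45281 probes. The deposited intensity values are on a linear scale and were neither normalized between arrays nor background-subtracted, as their lowest values (66.4 to 71.3), their medians (79.8 to 83.9) and their maxima (9172 to 13035) showed. The scanner software, the way the authors made the detection p-values, the sort and dissociation protocols, the time after infarction and the number of animals per array are not given in the sources used here. The series matrix holds intensity values, also linear and not centred, that the authors had brought to a common distribution over the 6 arrays (medians between 81.5053 and 81.5146, the same maximum of 11604 on each array). Its columns had the rank order of 1 signal column each. In 2 columns this was the column of the same label, and in the other 4 (both MI heart and both peritoneal arrays) it was the other replicate of the same group, so replicate numbers of these groups are swapped between the tables. The replicate numbers used here are those of the non-normalized table, and groups are the same in both tables. The number of columns with values per sample that were not used is 0.

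Signals were processed with limma 3.58.1 in R 4.3.3. The function neqc corrected the background with negative controls inferred from the detection p-values, added an offset of 16, applied quantile normalization and took log2. A probe was kept if its detection p was under 0.05 on both arrays of at least 1 group, which left 14817 probes. The platform table gave 1 gene symbol for 34885 probes, several for 18 and none for 10378. Entrez identifiers of 34807 probes were found in the reference gene table, and the symbol of 0 probes changed through it. For each symbol the probe with the highest mean over the 6 arrays was used, and unnamed probes were tested on their own, giving 8244 named genes and 2289 unnamed probes, or 10533 tests. The position of genes in the genome was not used.

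Group means were fitted over all 6 arrays with lmFit and eBayes, with 3 residual and 5.79 prior degrees of freedom. The 3 comparisons were tested with limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over the 10533 tests of each comparison and a threshold of 0.05. A gene was called above background in a group if its detection p was under 0.05 on at least 1 array. Where no probe of a gene was above background in the dimmer group, the fold is a lower bound, computed against the lowest normalized value of any probe above background on each array of that group, or the gene's own value if higher. It uses the mean of the brighter group, takes no account of the spread between arrays and is not a confidence limit. The same bound is given for named genes above background on 1 array only of the dimmer group whose value on the other array lay under that floor. Such bounds apply to 118, 491 and 363 called genes in the 3 comparisons in the order of the report. The median difference of all tested genes was between -0.05 and -0.00 on the log2 scale. With the replicate numbers of the non-normalized table, correlations of replicate deviations between groups were 0.08, 0.18 and 0.17, so same-numbered arrays of different groups were tied only weakly.

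Before the data were examined, 32 gene lists were fixed from textbook knowledge, among them markers of other cell types. Counts of members refer to those past the detection filter. Of the markers on the array, these were 3 of 16 for endothelium, 7 of 18 for fibroblasts and 10 of 17 for cardiomyocytes. They were 6 of 11 for smooth muscle and pericytes, 4 of 9 for B cells, 4 of 13 for neutrophils and 4 of 12 for dendritic cells. The others were not above background on both arrays of any group. The 28 lists with at least 3 tested members were tested with limma's camera, a competitive test, with the correlation between genes preset at 0.01 and, as an alternative, estimated from the residuals. Their p-values were adjusted over the 84 tests of all lists and comparisons. Members called are counted over all genes tested and also adjusted over the list alone. With the preset value camera called 16, 12 and 16 lists in the 3 comparisons, with 18, 14 and 16 at an unadjusted p under 0.05. With the estimated correlation it called 0 of the 84 tests, with 6, 6 and 9 at an unadjusted p under 0.05. The genes that the text names follow a rule that was also fixed then. In each comparison it takes the 6 genes with the largest difference per direction among called named genes above background in both groups whose replicates do not overlap, and the 4 genes per direction with the largest bound. It adds the 4 members of each list with the smallest adjusted p, and the gate genes Mrc1, Adgre1 and Itgam. Xist and Y-linked genes are left out. Genes named outside this rule are said to be so. A few list members with the next smallest p stand in the plot of named genes.

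The fit and the list test were run on simulated log2 values drawn around the real gene means and spreads. Each of 20 simulations of 10533 genes held 200 changed genes. Background correction, normalization, the detection filter, the choice of probe and the correlation between genes were not simulated. At a 1.5-fold change 21.7% were recovered, at a 2-fold change 90.0% and at a 4-fold change 99.9%, and 5.68% of calls were false. With no change, 0 genes were called. A list of 14 genes shifted 2-fold had an unadjusted p under 0.05 in 20 of 20 simulations with either correlation, and an unshifted list in 0. The simulated genes were independent, whereas the correlation estimated for the glycolysis list was 0.418. These runs therefore cannot show how often the preset value calls an unshifted list of correlated genes. Multiplied by the 84 tests, as for a single true list, the p of the shifted list stayed under 0.05 in 20 of 20 with the preset correlation and in 0 of 20 with the estimated one. A lone list with such a shift would therefore not be called with the estimated correlation. Several shifted lists at once were not simulated.

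The alternatives fixed beforehand were a normexp background without controls with an offset of 50, no background correction, median scaling or cyclic loess in place of quantiles, the series matrix values, no filter, a detection p under 0.01 on all arrays, an intensity trend with a robust prior, only the 4 arrays compared, the replicate number as a block, every probe on its own, the mean of a gene's probes, a 2-fold threshold, the estimated correlation, and each array left out in turn. With 1 array left out, the lone array of its group was assumed to vary like those of the other groups. A block by chip or slide was planned if the files named one, and they name none.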

Results

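Gene expression was measured with bead arrays in M2-like macrophages, defined in the series title as cells positive for CD206, F4/80 and CD11b, from C57BL/6 mice aged 10 weeks. The 6 arrays fell into 3 groups of 2 arrays: cells from the intact heart, from the heart with myocardial infarction (MI heart) and from the peritoneal cavity. Between 12433 and 14606 of the 45281 probes were above background on an array, or 27.5% to 32.3%, and the median raw signal lay between 79.8 and 83.9. The fewest probes above background were on intact heart replicate 1 (12433), then 13397 on intact heart replicate 2, 14023 and 14473 on the MI heart arrays and 14091 and 14606 on the peritoneal arrays. Across genes of single arrays, which are not independent replicates, the correlation of normalized values was 0.963 within intact heart, 0.980 within MI heart and 0.977 within peritoneal cavity. It was between 0.918 and 0.928 for pairs of intact and MI heart arrays, between 0.861 and 0.870 for MI heart and peritoneal arrays, and between 0.827 and 0.835 for intact heart and peritoneal arrays. All differences below are log2 differences with their standard errors (± SE, n = 2 arrays per group), or bounds on the fold where a gene was not above background on 1 or both arrays of the dimmer group and its value there lay under the floor. The number of arrays limits the precision, and the labels do not say whether the arrays of a group held cells of separate animals, so the p-values measure a spread between arrays that may be technical.

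The first comparison set M2-like macrophages of the MI heart against those of the intact heart. No group is labelled as sham-operated. Words such as rose and fell mean differences between the groups, whose mix of cells may also differ. In the MI heart 11 of 14 glycolysis genes and 7 of 20 repair genes were higher than in the intact heart, with 0 and 1 lower. Of immediate early and dissociation stress genes 8 of 17 were lower, and of resident heart macrophage genes 8 of 19, with 0 and 1 higher. These 4 lists were called with a preset correlation between genes, but none with an estimated one (adjusted p between 0.187 and 0.205). Arg1, which encodes the enzyme arginase 1 and is widely used as a marker of alternative activation, was at least 18.9-fold higher. Gpnmb, a membrane glycoprotein of macrophages in damaged tissue, was 14.3-fold higher (log2 difference 3.84 ± 0.27, adjusted p = 0.000138). The acute-phase protein gene Saa3 was at least 58.5-fold higher (adjusted p = 4.35e-05). In the other direction, the inducible heat-shock chaperone gene Hspa1b was 7.17-fold lower in the MI heart (-2.84 ± 0.18, adjusted p = 8.59e-05).

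The next largest increases among genes above background on at least 1 array of both groups were in F10, which encodes coagulation factor X (4.16 ± 0.28, adjusted p = 0.000127), and Acod1, the enzyme that makes itaconate (at least 10.1-fold, adjusted p = 0.000434). Pdpn, the membrane glycoprotein podoplanin, was at least 10.1-fold higher (adjusted p = 4.35e-05) and Thbs1, the matrix protein thrombospondin 1, at least 7.96-fold (adjusted p = 0.000271). Among genes not above background in the intact heart, the receptor gene Cd300lf was at least 10.7-fold higher and Igf2r, the receptor for mannose 6-phosphate and insulin-like growth factor 2, at least 9.83-fold higher. Chil3, a chitinase-like protein of alternatively activated macrophages, was at least 8.05-fold higher by the mean of the MI heart arrays, which lay far apart (mean 7.50, SD 1.10). This call was lost without background correction, with the series matrix values and with no filter. The largest decreases after Hspa1b were in Serpinf1, a secreted inhibitor of vessel growth (-2.65 ± 0.19, adjusted p = 0.000138), and Dcbld2 (-2.62 ± 0.18, adjusted p = 0.000127). Bag3, a partner of heat-shock chaperones, fell (-2.11 ± 0.21, adjusted p = 0.000943). Of the 10533 genes and unnamed probes tested, 481 were higher and 524 lower in the MI heart at an adjusted p under 0.05. An unadjusted p under that level was reached by 2649. With arrays scaled by their medians in place of quantile normalization, 629 were higher and 399 lower, so that 61.2% of calls were increases as against 47.9%. The counts fell most with 1 MI heart array left out, and less with 1 peritoneal or intact heart array left out. All groups share 1 estimate of the spread, which may be too small for the intact heart, whose replicates differed most. The SD of the difference between replicates was 0.365 there, 0.272 in the MI heart and 0.287 in the peritoneal cavity. Why the counts moved was not tested.

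**Figure D1:**
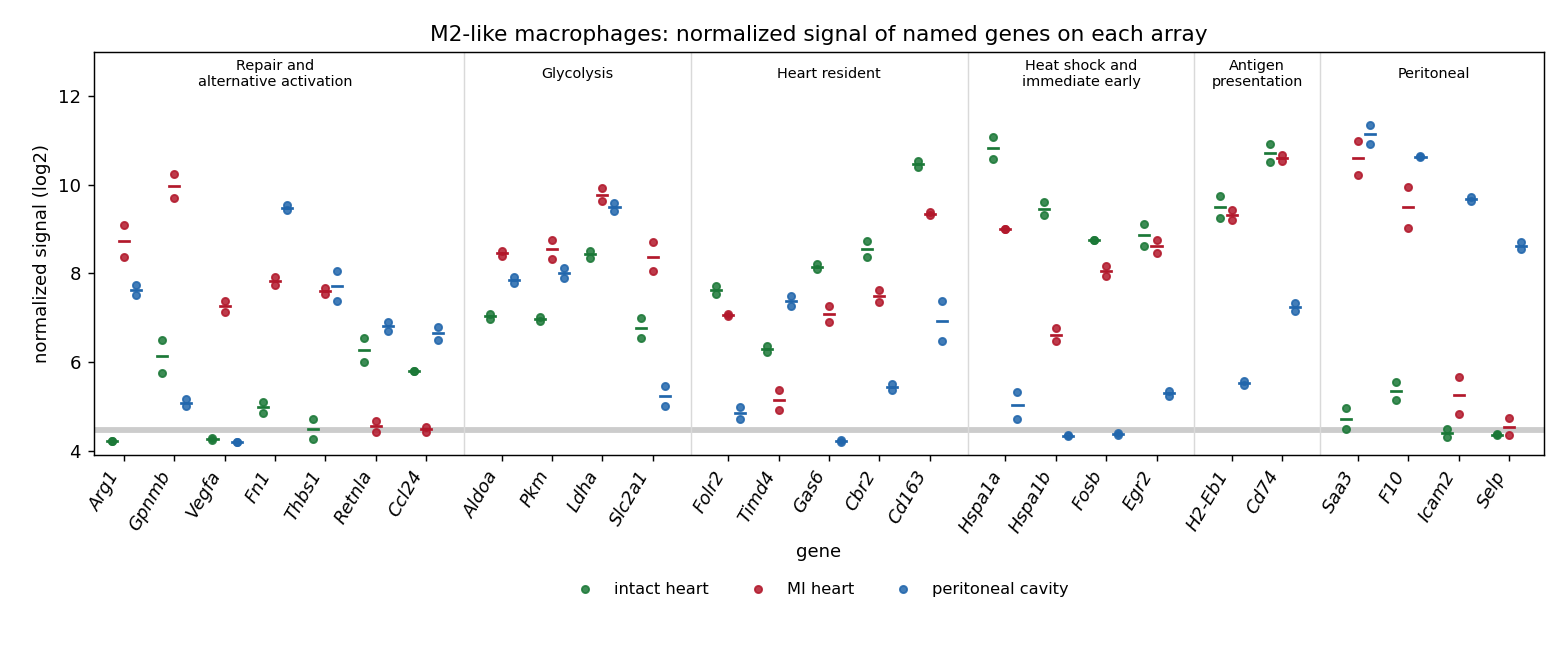
Normalized log2 signal of named genes on each array. Points are single arrays (n = 2 per group), short bars are group means, colors are the 3 groups, and the grey band spans the lowest values of probes above background on the 6 arrays (4.42 to 4.52). Arg1 lay at the background level in the intact heart and above the peritoneal level in the MI heart.

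Glycolysis genes, some hypoxia response genes and a few oxidative phosphorylation genes were higher in the MI heart. Of 14 tested glycolysis genes, 11 were higher, 0 lower and 3 not called, with 12 higher when adjusted over the list alone. The list was called by a competitive gene list test (adjusted p = 1.29e-09; adjusted p = 0.205 with an estimated correlation). Aldoa, the glycolytic enzyme aldolase A, rose by 1.42 ± 0.16 (adjusted p = 0.00131) and Pkm, which encodes pyruvate kinase, by 1.58 ± 0.19 (adjusted p = 0.00205). The hypoxia response list had 6 of 11 tested members higher, 1 lower and 4 not called, with the same 6 and 1 adjusted over the list alone. It was called too (adjusted p = 0.00254; adjusted p = 0.205 with an estimated correlation). Its members included Vegfa, the vessel growth factor, at least 6.76-fold higher, and Hif1a, a subunit of the oxygen-sensing transcription factor (1.15 ± 0.15, adjusted p = 0.00296). Of 19 oxidative phosphorylation genes, 4 were higher, 0 lower and 15 not called, and 8 were higher adjusted over the list alone. The list was called (adjusted p = 0.000336; adjusted p = 0.187 with an estimated correlation). The largest of these increases was in Cox5a, a subunit of cytochrome c oxidase (1.39 ± 0.17, adjusted p = 0.00197). Cox5a kept its call under all 17 alternatives. The other called members, Atp5o, Cox7b and Sdhd, lost theirs under 7, 3 and 2 of them.

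Some repair genes rose, while the alternative activation list went both ways. In the tissue repair and growth factor list, 7 of 20 members were higher, 1 lower and 12 not called, and 9 were higher and 4 lower adjusted over the list alone. The test called the list (adjusted p = 0.00114; adjusted p = 0.187 with an estimated correlation). Besides Gpnmb, Thbs1 and Vegfa, the higher members included Fn1, the matrix protein fibronectin (2.84 ± 0.17, adjusted p = 5.87e-05), and Mmp14, a membrane-bound matrix protease (2.54 ± 0.18, adjusted p = 0.000158). Of 16 alternative activation genes, 4 were higher, 5 lower and 7 not called, and 7 were higher and 5 lower adjusted over the list alone. There was no call for the list (adjusted p = 0.526; adjusted p = 0.627 with an estimated correlation). Tgm2, a crosslinking transglutaminase, rose by 2.77 ± 0.19 (adjusted p = 0.000127) beside Arg1. Ccl24, a chemokine for eosinophils, was at least 2.47-fold lower (adjusted p = 0.00248). Retnla, another marker gene of alternative activation, was at least 3.29-fold lower (adjusted p = 0.00206; adjusted p = 0.0593 without MI heart replicate 1). The fibroblast and collagen markers moved with these groups, with 4 of 7 higher, 0 lower and 3 not called, and 4 higher adjusted over the list alone. Their list was called (adjusted p = 0.000527; adjusted p = 0.197 with an estimated correlation), and the matrix protein gene Sparc rose by 1.32 ± 0.16 (adjusted p = 0.00212). Sparc kept its call under all 16 alternatives. The other called markers, Bgn, Col1a1 and Col5a1, lost theirs under 3, 2 and 11 of them.

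Some genes of resident heart macrophages and some stress genes fell. In the list of resident heart or interstitial macrophages, 8 of 19 members were lower, 1 higher and 10 not called, and 12 were lower and 1 higher adjusted over the list alone. As a list they were called as lower (adjusted p = 1.13e-05; adjusted p = 0.205 with an estimated correlation). Gas6, a bridging protein for apoptotic cell uptake, was lower (-1.06 ± 0.17, adjusted p = 0.0077; adjusted p = 0.0823 without MI heart replicate 1). Timd4, a receptor for phosphatidylserine, was lower too (-1.15 ± 0.19, adjusted p = 0.00894; adjusted p = 0.0931 without MI heart replicate 2 and 0.0678 with no filter). The member that rose was the chemokine gene Ccl8, at least 3.61-fold higher. Of 17 immediate early and dissociation stress genes, 8 were lower, 0 higher and 9 not called, with 10 lower adjusted over the list alone. This list was called as lower (adjusted p = 2.12e-06; adjusted p = 0.187 with an estimated correlation). Beside Hspa1b it held Hsph1, another heat-shock protein gene (-1.94 ± 0.22, adjusted p = 0.0014). Cardiomyocyte markers moved with these groups, with 2 of 10 lower, 0 higher and 8 not called, and 2 lower adjusted over the list alone. Their list was called as lower (adjusted p = 0.00601; adjusted p = 0.187 with an estimated correlation). These were the muscle myosin light chain genes Myl2 (-1.36 ± 0.21, adjusted p = 0.00584) and Myl3 (-0.84 ± 0.16, adjusted p = 0.0157). Without MI heart replicate 1 their adjusted p values were 0.0615 and 0.0907, and without replicate 2 they were 0.0929 and 0.132. Myl2 also lost its call with no filter (adjusted p = 0.0625), and Myl3 with no background correction (adjusted p = 0.0556) and the series matrix values (adjusted p = 0.0539).

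Lists of monocyte, large peritoneal macrophage, interferon response, classical activation and chemokine genes had a few members each that rose. The MHC class II list had none. Of 10 monocyte genes, 4 were higher, 1 lower and 5 not called, with 5 higher and 1 lower adjusted over the list alone. The list was called as higher (adjusted p = 0.000595; adjusted p = 0.187 with an estimated correlation). Plac8, a gene of circulating monocytes, was at least 6.14-fold higher and Hp, which encodes haptoglobin, at least 3.44-fold higher. The Hp call was lost without background correction, with the series matrix values and with no filter. Of 14 large peritoneal macrophage genes, 4 were higher, 0 lower and 10 not called, with 6 higher adjusted over the list alone. Saa3 and F10 were among the 4, and the list was called (adjusted p = 0.000666; adjusted p = 0.283 with an estimated correlation). The interferon response list had 3 of 11 members higher, 1 lower and 7 not called, with 5 higher and 1 lower adjusted over the list alone. It was called as higher (adjusted p = 0.000434; adjusted p = 0.223 with an estimated correlation). Its higher members included the antiviral genes Rsad2 (1.58 ± 0.16, adjusted p = 0.000795) and Ifit2 (1.39 ± 0.16, adjusted p = 0.00141). Of 13 genes of classical activation, 4 were higher, 0 lower and 9 not called, the same adjusted over the list alone. The call for this list (adjusted p = 0.0323; adjusted p = 0.473 with an estimated correlation) was lost without intact heart replicate 2 (adjusted p = 0.0636), without MI heart replicate 1 (adjusted p = 0.26) and with every probe on its own (adjusted p = 0.225). With only probes at a detection p under 0.01 on all arrays, the monocyte, interferon and classical activation lists were not called (adjusted p = 0.502, 0.875 and 0.979). Ptgs2, the inducible cyclooxygenase, rose by 1.84 ± 0.24 (adjusted p = 0.0027; adjusted p = 0.056 with no filter). Of 16 chemokine genes, 3 were higher, 0 lower and 13 not called, with 4 higher and 2 lower adjusted over the list alone. The chemokine list was not called (adjusted p = 0.0866; adjusted p = 0.36 with an estimated correlation). Of 11 MHC class II antigen presentation genes, 0 were higher, 1 lower and 10 not called, the same adjusted over the list alone. Their list was not called (adjusted p = 0.303; adjusted p = 0.542 with an estimated correlation). Among markers of other leukocytes, S100a9, a neutrophil gene, was at least 3.56-fold higher (adjusted p = 0.0358). With any 1 array other than MI heart replicate 2 left out its adjusted p lay between 0.0654 and 0.13, and under 5 other alternatives between 0.0872 and 0.274. Hdc, the histamine-forming enzyme listed as a mast cell marker, rose by 2.24 ± 0.27 (adjusted p = 0.00187; adjusted p = 0.0523 with no filter). The gate genes, used to choose the cells, differed by -0.69 ± 0.19 for Mrc1 (CD206; adjusted p = 0.0541), 0.30 ± 0.25 for Adgre1 (F4/80; adjusted p = 0.525) and 1.02 ± 0.24 for Itgam (CD11b; adjusted p = 0.0301). Mrc1 lay near the threshold and was called as lower under 5 of 17 alternatives. With any 1 array other than intact heart replicate 1 left out, the adjusted p of Itgam lay between 0.0849 and 0.235, and under 4 other alternatives between 0.066 and 0.172.

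**Figure D2:**
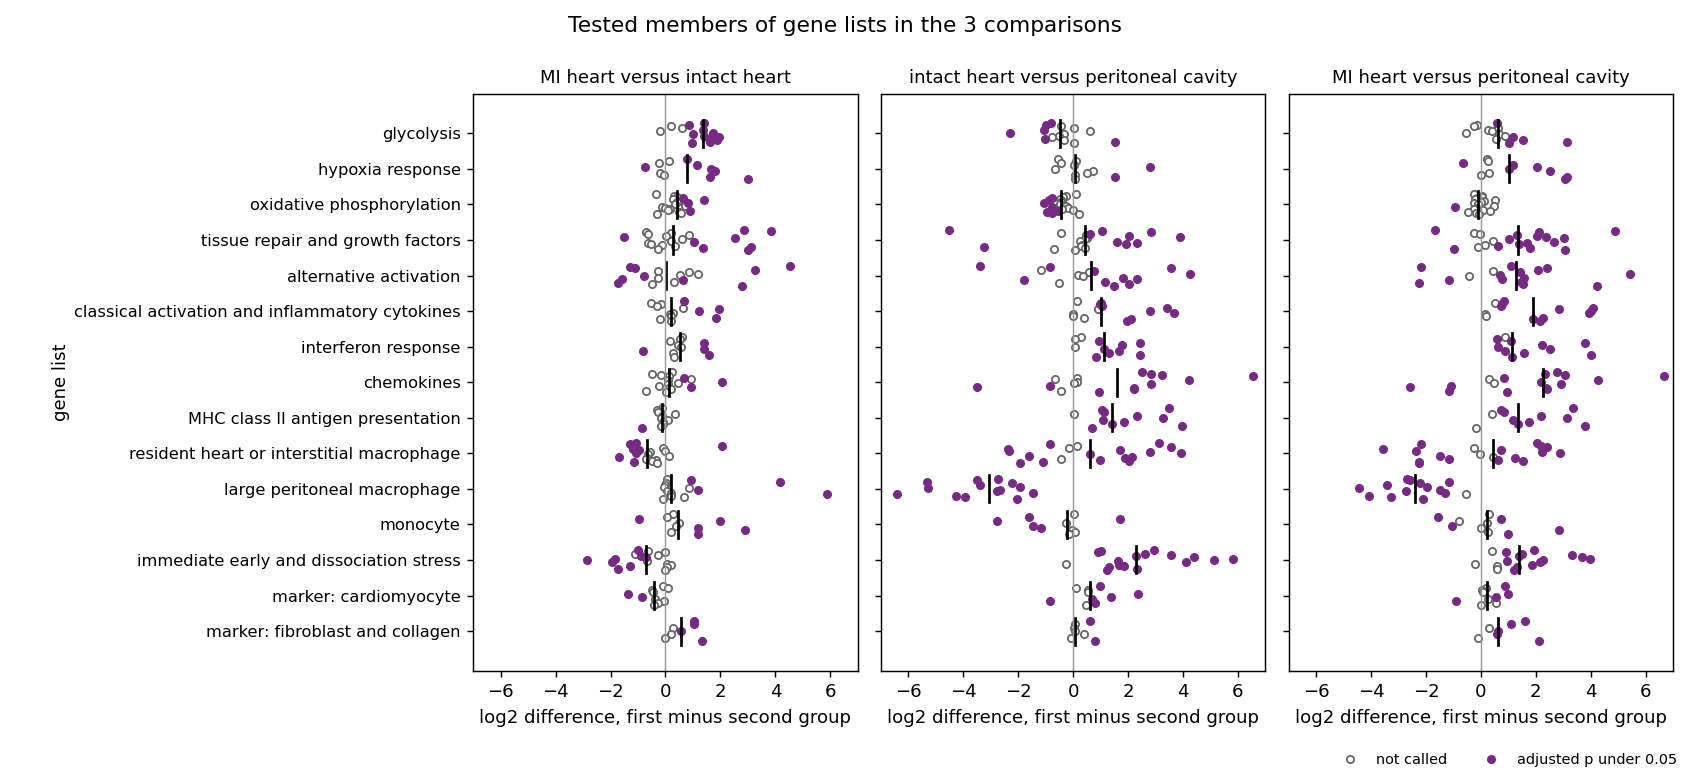
Log2 differences of the tested members of 15 gene lists in the 3 comparisons, as first minus second group. Points are genes, filled where the adjusted p was under 0.05, and black bars are list medians, with glycolysis members mostly above 0 in MI heart versus intact heart and the large peritoneal macrophage list below 0 in both comparisons with peritoneal cavity.

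The second comparison set macrophages of the intact heart against those of the peritoneal cavity. In the intact heart 16 of 17 immediate early and dissociation stress genes, 10 of 11 class II antigen presentation genes and 9 of 16 chemokine genes were higher, with 0, 0 and 2 lower. With an estimated correlation none of these lists was called (adjusted p = 0.187 for each). Ccl4, a chemokine for monocytes and T cells, was at least 87.9-fold higher (adjusted p = 2.21e-07), and Cd83, an activation marker of antigen-presenting cells, was at least 54.3-fold higher. Peritoneal macrophages carried far more Saa3 (at least 84.9-fold lower in the intact heart, adjusted p = 2.42e-06) and more Slpi, a secreted protease inhibitor (at least 67.0-fold lower, adjusted p = 3.62e-06). The gate gene Mrc1 was 21.7-fold higher in the intact heart (4.44 ± 0.19, adjusted p = 2.29e-06), although the series title gives its protein as a marker of the cells of all groups. Itgam went the other way and was 4.21-fold lower (-2.07 ± 0.24, adjusted p = 0.000326). Adgre1 was not called (-0.43 ± 0.25, adjusted p = 0.249).

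All 14 tested genes of large peritoneal macrophages were lower in the intact heart, and all 14 were lower adjusted over the list alone (list adjusted p = 5.04e-16; adjusted p = 0.187 with an estimated correlation). Examples were F10 (-5.30 ± 0.28, adjusted p = 4.82e-06) and the adhesion gene Icam2 (at least 36.1-fold lower, adjusted p = 3.08e-06). The selectin gene Selp was at least 17.5-fold lower and Serpinb2, a plasminogen activator inhibitor, at least 12.7-fold lower. Of 17 immediate early and dissociation stress genes, 16 were higher, 0 lower and 1 not called, with 16 higher adjusted over the list alone. Their list was called (adjusted p = 3e-14; adjusted p = 0.187 with an estimated correlation). Hspa1a, an inducible heat-shock gene, was 56.5-fold higher (5.82 ± 0.24, adjusted p = 2.29e-06), and Fosb, an immediate early transcription factor gene, at least 20.1-fold higher. Markers of cardiomyocytes moved with this group, with 5 of 10 higher, 1 lower and 4 not called, and 8 higher and 1 lower adjusted over the list alone. The marker list was called (adjusted p = 0.00247; adjusted p = 0.187 with an estimated correlation). Myl2 was at least 4.19-fold and Myl3 at least 2.16-fold higher. Smooth muscle and pericyte markers were higher for 2 of 6 members, lower for 0 and not called for 4, with 4 higher adjusted over the list alone (adjusted p = 0.0283; adjusted p = 0.223 with an estimated correlation). This list call was lost without intact heart replicate 1 (adjusted p = 0.0862), without peritoneal replicate 2 (adjusted p = 0.155) and with no filter (adjusted p = 0.134).

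Most tested genes of antigen presentation and of 3 inflammatory lists were higher in the intact heart. Like those of the stress genes, these differences may reflect handling or organ, which cannot be told apart because each group comes from 1 site. Of 11 MHC class II genes, 10 were higher, 0 lower and 1 not called, with 10 higher adjusted over the list alone. Their list was called (adjusted p = 3.92e-08; adjusted p = 0.187 with an estimated correlation). They included H2-Eb1, which encodes a class II chain (3.97 ± 0.20, adjusted p = 3.62e-06), and Cd74, the invariant chain (3.48 ± 0.19, adjusted p = 5.39e-06). Other cells that carry class II had markers that moved the same way, with 2 of 4 B cell and 2 of 4 dendritic cell markers higher, 0 lower and 2 not called in each, the same adjusted over the list alone. Among the called markers, Ebf1 of B cells and Batf3 of dendritic cells lost their calls under 10 and 11 of 16 alternatives. These marker lists were not called (adjusted p = 0.0954 and 0.0824; adjusted p = 0.291 and 0.275 with an estimated correlation). Of 16 chemokine genes, 9 were higher, 2 lower and 5 not called, with 9 higher and 3 lower adjusted over the list alone. The chemokine list was called (adjusted p = 0.000319; adjusted p = 0.187 with an estimated correlation). Ccl7, a chemokine for monocytes, was at least 15.4-fold higher and Cxcl13, a chemokine for B cells, at least 9.44-fold lower. Of 13 classical activation genes, 8 were higher, 0 lower and 5 not called, with 8 higher adjusted over the list alone. This list was called (adjusted p = 6.08e-06; adjusted p = 0.252 with an estimated correlation), and the interleukin gene Il1b was at least 11.2-fold higher. Of 11 interferon response genes, 8 were higher, 0 lower and 3 not called, with 8 higher adjusted over the list alone. The interferon list was called (adjusted p = 7.76e-06; adjusted p = 0.187 with an estimated correlation), and Rsad2 was at least 4.97-fold higher.

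Genes of repair, alternative activation and tissue residence went both ways. Of 20 tissue repair genes, 8 were higher, 2 lower and 10 not called, with 11 higher and 4 lower adjusted over the list alone. The list was called (adjusted p = 0.00497; adjusted p = 0.187 with an estimated correlation), but not with a detection p under 0.01 on all arrays (adjusted p = 0.195) or with every probe on its own (adjusted p = 0.0549). Hbegf, a growth factor of the EGF family, was higher (2.83, adjusted p = 5.37e-05), whereas Fn1 was 22.7-fold lower (-4.50 ± 0.17, adjusted p = 1.41e-06). Of 16 alternative activation genes, 8 were higher, 3 lower and 5 not called, with 8 higher and 5 lower adjusted over the list alone. Their list was called (adjusted p = 0.041; adjusted p = 0.273 with an estimated correlation). This list lost its call without intact heart replicate 2 (adjusted p = 0.0932), MI heart replicate 1 (adjusted p = 0.062) or MI heart replicate 2 (adjusted p = 0.0646). It was also lost with median scaling (adjusted p = 0.0512), no filter (adjusted p = 0.0525), the normexp background without controls (adjusted p = 0.0527), only the 4 arrays (adjusted p = 0.0577), no background correction (adjusted p = 0.0611) and the series matrix values (adjusted p = 0.0626). The scavenger receptor gene Cd163 was higher (3.54 ± 0.27, adjusted p = 2.88e-05). Il10, an anti-inflammatory cytokine, was at least 15.4-fold higher and Arg1 at least 8.75-fold lower. Of 19 resident heart or interstitial macrophage genes, 10 were higher, 6 lower and 3 not called, the same adjusted over the list alone. There was no call for this list (adjusted p = 0.0959; adjusted p = 0.473 with an estimated correlation). Gas6 was at least 13.2-fold higher, and Folr2, a folate receptor of resident macrophages, was higher by 2.78 ± 0.17 (adjusted p = 8.88e-06). Oxidative phosphorylation genes were lower for 7 of 19 members, higher for 0 and not called for 12, with 8 lower adjusted over the list alone. Their list was called as lower (adjusted p = 0.000966; adjusted p = 0.187 with an estimated correlation). Of 14 glycolysis genes, 5 were lower, 1 higher and 8 not called, with 6 lower and 1 higher adjusted over the list alone. The glycolysis list was called as lower (adjusted p = 0.0422; adjusted p = 0.51 with an estimated correlation). The call was lost without intact heart replicate 1 (adjusted p = 0.0935), MI heart replicate 1 (adjusted p = 0.062), peritoneal replicate 1 (adjusted p = 0.0583) or peritoneal replicate 2 (adjusted p = 0.0888), and with every probe on its own (adjusted p = 0.205), the mean of a gene's probes (adjusted p = 0.136) or cyclic loess (adjusted p = 0.0506). Of 10 monocyte genes, 1 was higher, 4 lower and 5 not called. Of 11 hypoxia response genes, 2 were higher, 0 lower and 9 not called, and of 7 fibroblast and collagen markers, 2 were higher, 0 lower and 5 not called. These counts were the same adjusted over the list alone, and none of these 3 lists was called (adjusted p = 0.0954, 0.303 and 0.182; adjusted p = 0.298, 0.505 and 0.461 with an estimated correlation). Hba-a1, a hemoglobin gene of red blood cells, was at least 9.02-fold lower in the intact heart (adjusted p = 9.23e-06), as was Hdc (-4.11 ± 0.27, adjusted p = 1.3e-05). Of 10533 tested, 1322 were higher and 1355 lower in the intact heart, and 3988 had an unadjusted p under 0.05. The counts fell to 702 and 638 without peritoneal replicate 1 and to 696 and 694 without peritoneal replicate 2.

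The third comparison set macrophages of the MI heart against those of the peritoneal cavity. In the MI heart 11 of 16 chemokine, 10 of 13 classical activation, 10 of 11 interferon response and 13 of 20 repair genes were higher, with 3, 0, 0 and 2 lower, and 13 of 14 large peritoneal macrophage genes were lower. None of these 5 lists was called with an estimated correlation (adjusted p between 0.187 and 0.191). Ccl4 was at least 95.9-fold higher (adjusted p = 4.8e-07), Gpnmb 29.7-fold higher (4.89 ± 0.27, adjusted p = 8.04e-06) and Tgm2 18.9-fold higher (4.24 ± 0.19, adjusted p = 2.82e-06). Il10 was at least 34.8-fold and Cd83 at least 34.0-fold higher. The largest decreases were in Icam2 (-4.43 ± 0.25, adjusted p = 8.11e-06), Selp (at least 16.5-fold lower, adjusted p = 2.82e-06) and Ptgis, the enzyme that makes prostacyclin, at least 18.4-fold lower. The gate gene Mrc1 was 13.5-fold higher (3.76 ± 0.19, adjusted p = 5.51e-06). Itgam was 2.07-fold lower (-1.05 ± 0.24, adjusted p = 0.015), a call lost under 5 of 17 alternatives. Adgre1 was not called (-0.14 ± 0.25, adjusted p = 0.777).

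Large peritoneal macrophage genes were lower for 13 of 14 members, higher for 0 and not called for 1, with 13 lower adjusted over the list alone. Their list had the smallest p (adjusted p = 5.09e-15; adjusted p = 0.187 with an estimated correlation). Of 17 immediate early and dissociation stress genes, 13 were higher, 0 lower and 4 not called, with 15 higher adjusted over the list alone. The list was called (adjusted p = 1.18e-12; adjusted p = 0.187 with an estimated correlation). Hspa1a was higher by 3.98 ± 0.24 (adjusted p = 1.02e-05) and Fosb was at least 12.3-fold higher. Interferon response genes were higher for 10 of 11 members, lower for 0 and not called for 1, with 11 higher adjusted over the list alone (adjusted p = 1.18e-10; adjusted p = 0.187 with an estimated correlation). Rsad2 was at least 14.9-fold and Ifit2 at least 12.2-fold higher. Classical activation genes were higher for 10 of 13 members, lower for 0 and not called for 3, with 11 higher adjusted over the list alone (adjusted p = 6.47e-10; adjusted p = 0.191 with an estimated correlation). The interleukin gene Il1a was higher by 4.03 ± 0.19 (adjusted p = 4.57e-06). MHC class II genes were higher for 9 of 11 members, lower for 0 and not called for 2, with 10 higher adjusted over the list alone (adjusted p = 2.41e-08; adjusted p = 0.187 with an estimated correlation). H2-Eb1 was higher by 3.80 ± 0.20 (adjusted p = 5.99e-06). Chemokine genes were higher for 11 of 16 members, lower for 3 and not called for 2, with 12 higher and 3 lower adjusted over the list alone (adjusted p = 6.18e-08; adjusted p = 0.187 with an estimated correlation). Ccl7 was at least 16.3-fold higher.

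Tissue repair genes were higher for 13 of 20 members, lower for 2 and not called for 5, the same adjusted over the list alone (adjusted p = 1.25e-07; adjusted p = 0.187 with an estimated correlation). Vegfa was at least 7.07-fold and Mmp14 at least 7.03-fold higher, and Osm, the cytokine oncostatin M, was higher by 2.65 ± 0.17 (adjusted p = 1.49e-05). Alternative activation genes were higher for 11 of 16 members, lower for 3 and not called for 2, with 11 higher and 4 lower adjusted over the list alone (adjusted p = 0.000936; adjusted p = 0.187 with an estimated correlation). Ccl24 (at least 4.46-fold, adjusted p = 4.27e-05) and Retnla (at least 4.76-fold, adjusted p = 0.000124) were lower. The hypoxia response list had 6 of 11 members higher, 1 lower and 4 not called, the same adjusted over the list alone (adjusted p = 9.92e-05; adjusted p = 0.187 with an estimated correlation). Slc2a1, a glucose transporter, was higher by 3.14 (adjusted p = 7.69e-05). Of 14 glycolysis genes, 5 were higher, 0 lower and 9 not called, with 9 higher adjusted over the list alone (adjusted p = 0.000966; adjusted p = 0.36 with an estimated correlation). This list call was lost without MI heart replicate 1 (adjusted p = 0.104). Of 19 oxidative phosphorylation genes, 0 were higher, 1 lower and 18 not called, the same adjusted over the list alone, and the list was not called (adjusted p = 0.645; adjusted p = 0.663 with an estimated correlation). Resident heart or interstitial macrophage genes were higher for 9 of 19 members, lower for 7 and not called for 3, the same adjusted over the list alone. Their list was not called (adjusted p = 0.516; adjusted p = 0.721 with an estimated correlation). Folr2 was higher (2.22 ± 0.17, adjusted p = 4.1e-05) and Ednrb, the endothelin receptor B gene, 11.9-fold lower (-3.58 ± 0.18, adjusted p = 5.67e-06). Of 10 monocyte genes, 3 were higher, 2 lower and 5 not called, with 3 higher and 3 lower adjusted over the list alone. The monocyte list was not called (adjusted p = 0.302; adjusted p = 0.461 with an estimated correlation), and Plac8 was at least 6.42-fold higher.

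Some markers of other cells moved with these groups, although most fibroblast, endothelial and B cell markers on the array did not pass the detection filter. Fibroblast and collagen markers were higher for 5 of 7 members, lower for 0 and not called for 2, with 5 higher adjusted over the list alone (adjusted p = 0.000261; adjusted p = 0.187 with an estimated correlation), and Sparc was at least 3.70-fold higher. Of 10 cardiomyocyte markers, 3 were higher, 1 lower and 6 not called, with 4 higher and 1 lower adjusted over the list alone. The called members Myl2, Myl3, Cox6a2 and Ryr2 lost their calls under 7, 7, 4 and 2 of 16 alternatives. Of 6 smooth muscle and pericyte markers, 0 were higher, 0 lower and 6 not called, the same adjusted over the list alone. Neither list was called (adjusted p = 0.0925 and 0.359; adjusted p = 0.275 and 0.483 with an estimated correlation). Of 3 endothelial markers, 1 was higher, 0 lower and 2 not called, with 2 higher adjusted over the list alone (adjusted p = 0.0269; adjusted p = 0.228 with an estimated correlation). This call was lost without intact heart replicate 1 (adjusted p = 0.0545), intact heart replicate 2 (adjusted p = 0.0673), MI heart replicate 1 (adjusted p = 0.062) or peritoneal replicate 2 (adjusted p = 0.155). Of 4 B cell markers, 1 was higher, 0 lower and 3 not called, with 2 higher adjusted over the list alone (adjusted p = 0.0435; adjusted p = 0.236 with an estimated correlation). The B cell call was lost without MI heart replicate 2 (adjusted p = 0.0717), without peritoneal replicate 2 (adjusted p = 0.0881), with the normexp background without controls (adjusted p = 0.0579), no background correction (adjusted p = 0.0611), the series matrix values (adjusted p = 0.0626) and no filter (adjusted p = 0.0862). Hba-a1 was lower in the MI heart (-3.31 ± 0.19, adjusted p = 9.66e-06), as was the hemoglobin gene Hbb-bs (-3.42 ± 0.30, adjusted p = 9.12e-05). Of 10533 tested, 966 were higher and 892 lower in the MI heart, and 3111 had an unadjusted p under 0.05. The counts fell to 533 and 384 without MI heart replicate 1, 510 and 342 without MI heart replicate 2, 481 and 399 without peritoneal replicate 1, and 483 and 423 without peritoneal replicate 2.

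Both heart groups differed from the peritoneal cavity in many of the same genes. Ccl4, Cd83, Ccl7, Fcrls, Slamf9 and the class II gene H2-Eb1 were among the 629 genes higher in both, and Icam2, Selp, Ptgis and Slpi among the 638 lower in both. These were 65.1% of the genes higher and 71.5% of those lower in the MI heart than in the peritoneal cavity. Both comparisons used the same peritoneal arrays, whose noise alone favours shared calls. In 100 simulations with these arrays on both sides and the MI heart differences dealt out at random over the genes, a test chosen after the counts were seen, at most 22.9% and 26.0% were shared. The simulations called more genes in the MI heart (medians 1505 and 1646) and shared at most 347 and 442. The shared counts were 382 and 324 without MI heart replicate 1, 369 and 292 without MI heart replicate 2, 331 and 308 without peritoneal replicate 1, and 331 and 336 without peritoneal replicate 2. The comparison of both hearts also crossed with the peritoneal cavity. Of the 481 genes higher in the MI than the intact heart, 227 were lower and 40 higher in the intact heart than in the peritoneal cavity. Saa3, F10, Thbs1 and Fn1 were among these 227. Of the 524 genes lower in the MI heart, 384 were higher and 13 lower in the intact heart than in the peritoneal cavity. These counts use the intact heart arrays on both sides, so noise in them alone favours opposite directions. This was also simulated 100 times after the counts were seen, with the changes between the hearts dealt out at random over the genes and the same intact arrays on both sides. Of the genes called higher in the MI heart, at most 26.3% were then lower in the intact heart than in the peritoneal cavity, beside 47.2% in the data. Of those called lower, at most 23.1% were higher there, beside 73.3%. Only shares compare, since the simulations called more genes (medians 1208 and 1305) and gave 228 to 331 and 241 to 315 crossing genes.

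**Figure D3:**
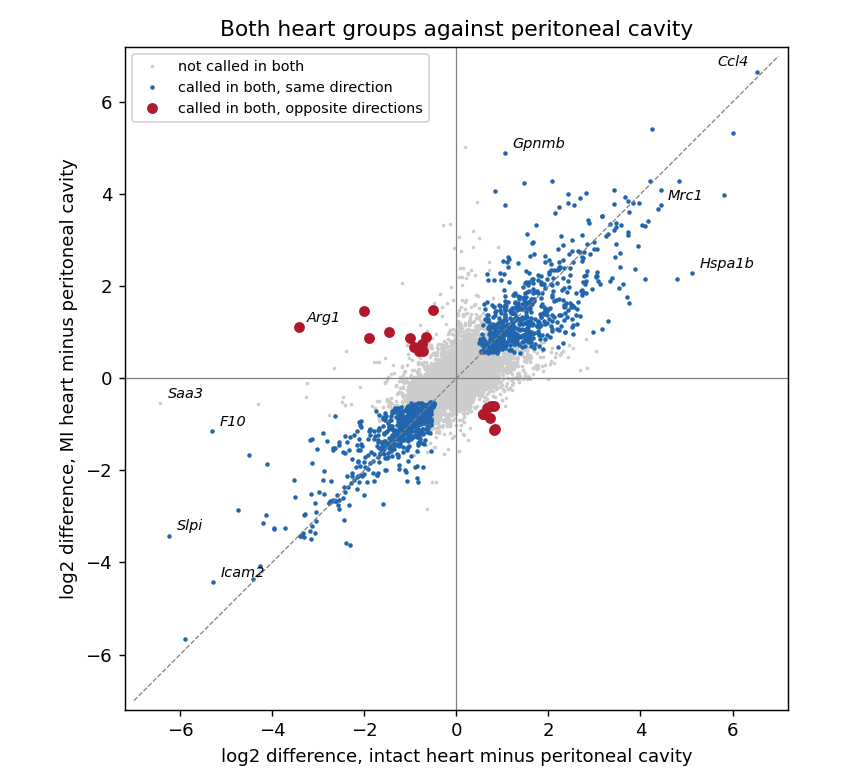
Log2 difference of each tested gene between intact heart and peritoneal cavity (horizontal) and between MI heart and peritoneal cavity (vertical). Points are genes, in blue where called in both with the same direction (629 higher and 638 lower) and in red where called in opposite directions, and the dashed line marks equal differences.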

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

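The tests of the 3 patterns below were chosen after the result was seen, except the correlations with a different intact heart array on each side, and the comparisons between groups were chosen before.

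Against the peritoneal cavity, 19 genes and unnamed probes were called in opposite directions in the 2 heart groups, and all 19 were also called between MI and intact heart, which follows where both differences are called with opposite signs and is no independent test. Of these, 8 were above the peritoneal level in the intact heart and below it in the MI heart, and 11 the other way round. Arg1 was higher in the MI than in the intact heart by 4.52 ± 0.23 on the log2 scale (adjusted p = 4.35e-05), and since it was not above background in the intact heart the bound is at least 18.9-fold. Its call between MI heart and peritoneal cavity (1.11 ± 0.23, adjusted p = 0.0112) was lost without MI heart replicate 1 (adjusted p = 0.0761), peritoneal replicate 1 (adjusted p = 0.13) or peritoneal replicate 2 (adjusted p = 0.0787), and with no filter (adjusted p = 0.11). The next genes were chosen after their values were seen, except Aldoa. Fpr2, a receptor for formyl peptides, was higher in the MI heart by 2.77 ± 0.23 (adjusted p = 0.00041), Adam8, a membrane protease, by 1.88 ± 0.18 (at least 3.51-fold, adjusted p = 0.000706) and Aldoa by 1.42 ± 0.16 (adjusted p = 0.00131). Gimap6, a GTPase of immune cells, differed by -1.93 ± 0.21 (at least 3.56-fold lower, adjusted p = 0.00131) and Wtip by -1.92 ± 0.18 (adjusted p = 0.00072). The opposite directions of these genes are fragile. Between MI heart and peritoneal cavity, Fpr2 (0.88 ± 0.23) lost its call without MI heart replicate 1 or either peritoneal array (adjusted p between 0.116 and 0.233), Adam8 (0.89 ± 0.18) and Aldoa (0.60 ± 0.16) without any 1 of the 4 arrays compared (0.0568 to 0.0859 and 0.0813 to 0.146), Gimap6 (-1.10 ± 0.21) without MI heart replicate 2 or either peritoneal array (0.0595 to 0.0894) and Wtip (-1.12 ± 0.18) without peritoneal replicate 2 (0.0526). Between intact heart and peritoneal cavity, Adam8 lost it without peritoneal replicate 1 (0.0504), Gimap6 without any 1 of the 4 arrays compared (0.0688 to 0.133) and Wtip without intact heart replicate 1 or either peritoneal array (0.0542 to 0.104). With no filter Fpr2 and Gimap6 lost their calls between MI heart and peritoneal cavity (0.192 and 0.0734), as did Gimap6 and Wtip between intact heart and peritoneal cavity (0.113 and 0.0553). In each of these genes the arrays of the MI and intact heart did not overlap, which holds by chance in 1 of 3 genes. The number of opposite calls was 7 with no filter, 12 with a detection p under 0.01 on all arrays, 2 at a 2-fold threshold, 5 without MI heart replicate 1, 6 without MI heart replicate 2, 2 without peritoneal replicate 1, 1 without peritoneal replicate 2, 14 without intact heart replicate 1 and 23 without intact heart replicate 2.

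The first pattern is that the list of immediate early and dissociation stress genes was called as higher in both hearts than in the peritoneal cavity and as lower in the MI than in the intact heart. The tables argue against normalization as the source of the second part. The list median of MI minus intact heart was -0.71 in the report. With median scaling or cyclic loess in place of quantiles it was -0.70 and -0.86. Over all 5 other background corrections, scalings and value tables, some of which kept a common distribution for all arrays, the median closest to 0 was -0.61. Handling before the RNA was made remains open, as the protocols are not given in the sources used here: the list median of MI heart minus peritoneal cavity was 1.38, so both hearts stood above. Handling and organ cannot be told apart here, because each group comes from 1 site. The same holds for the chemokine, classical activation, interferon and class II lists against the peritoneal cavity. An effect of infarction on these genes also stays open and was not tested apart from handling.

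The second pattern is that genes higher in the peritoneal cavity than in the intact heart were often higher in the MI than in the intact heart. Peritoneal-type cells mixed into the MI heart samples would raise all such genes by the same share, but over 30 genes at least 8-fold higher in the peritoneal cavity the implied share of peritoneal RNA had a median of 7.27% and quartiles of 1.60% and 27.0%. It was under 5% for 13 genes and over 40% for 5. Examples were 228% for Arg1, 68.4% for Saa3 and 43.7% for F10, but 2.11% for Icam2, 0.739% for Selp and 0.196% for Ptgis. Arg1, Selp and Ptgis were not above background in the intact heart, nor Ptgis in the MI heart, so their shares are approximate. The spread of the shares argues against mixing as the whole cause. Noise of single intact arrays is not the whole cause either. With a different intact array on each side, the correlation across genes of MI minus intact with peritoneal minus intact was still 0.315 and 0.385. The 0.478 with the same arrays decides nothing, since sharing them gave up to 0.517 in simulations with no change. An offset common to both intact arrays stays on both sides in all of these and was not tested. Both intact arrays had the fewest probes above background (12433 and 13397, against 14023 to 14606 on the others). More monocyte-derived cells in the MI heart may contribute, but the monocyte list decides nothing (adjusted p = 0.187 with an estimated correlation, 0.000595 with the preset one).

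The third pattern is that 11 of 14 glycolysis genes were higher in the MI than in the intact heart. The list median of 1.37 lay at percentile 100 of 10000 random lists matched on mean level, whose highest median was 0.46. This cannot decide on brighter MI arrays. Quantile normalization gives every array the same distribution, so such lists lie near 0 whatever the raw brightness. The list was also picked for its increases, and the random lists ignore the correlation between its genes. The tables argue against normalization as the source of the increases. The median was 1.49 with median scaling and 1.31 with cyclic loess in place of quantiles. Over all 5 alternatives, some of which kept a common distribution for all arrays, it was 0.83 or more. A response to low oxygen is a candidate explanation that remains open: the hypoxia list without glycolysis members had 5 of 10 members higher and 1 lower, with adjusted p = 0.0119 with the preset and 0.253 with an estimated correlation.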

How the results depend on the processing

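Of the counts under alternatives, 163 stayed within 1.5 times the reported count and 65 did not. Genes called higher and lower between MI and intact heart (481 and 524) numbered 200 and 222 with no filter, 248 and 322 with a detection p under 0.01 on all arrays, 289 and 305 with only the 4 arrays compared, and 227 and 209 at a 2-fold threshold. Lower genes numbered 332 with no background correction and 329 with the series matrix values. Between intact heart and peritoneal cavity (1322 and 1355) the counts were 771 and 757 with a detection p under 0.01 on all arrays and 690 and 480 at 2-fold. Between MI heart and peritoneal cavity (966 and 892) they were 537 and 517 with that detection p and 556 and 364 at 2-fold, with 583 higher with no filter. Shared calls (629 higher, 638 lower) were 380 and 328 with that detection p and 376 and 265 at 2-fold, with 377 higher with no filter. No filter adds tests and the stricter detection p removes genes. A 2-fold threshold removes calls by construction. With only the 4 arrays compared, the counts between MI heart and peritoneal cavity rose to 1119 and 1050. The cause was not tested for the other settings. With a detection p under 0.01 on all arrays, 7 gene lists were called between MI and intact heart and 10 between MI heart and peritoneal cavity, against 16 and 16 reported. Of the missing calls, 5 and 2 were lost and 4 and 4 had too few members left for a test. With an estimated correlation, 0, 0 and 0 lists were called in the 3 comparisons.

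With each array left out in turn, the genes higher ranged from 92 to 448 and those lower from 67 to 496 between MI and intact heart, from 696 to 1214 and 638 to 1173 between intact heart and peritoneal cavity, from 481 to 1093 and 342 to 1039 between MI heart and peritoneal cavity, and from 331 to 638 and 292 to 625 for shared calls. The counts between MI and intact heart were 92 and 67 without MI heart replicate 1, 131 and 79 without MI heart replicate 2, 258 and 270 without peritoneal replicate 1, and 247 and 257 without peritoneal replicate 2, and 306 were higher without intact heart replicate 1. Those between intact heart and peritoneal cavity were 702 and 638 without peritoneal replicate 1 and 696 and 694 without peritoneal replicate 2. The lone array of its group is assumed to vary like the others. Calls between MI heart and peritoneal cavity rose without either intact heart array, and the cause of these moves was not tested. With the replicate block, 628 were higher and 692 lower between MI and intact heart, 1475 and 1556 between intact heart and peritoneal cavity, and 1099 and 1049 between MI heart and peritoneal cavity. That block used the replicate numbers of the non-normalized table, which are swapped for MI heart and peritoneal arrays in the series matrix. A block with the other numbering was not run. A block by chip or slide was not run because the files name none.

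Of 386 differences of named genes followed, 287 were called, and 187 of these were called under every alternative that gave a value. A change of sign was counted only where the reported or the alternative value was called. By that count, 383 of the 386 had none. Of the 6329 alternative values, 435 lost a call, 58 gained one and 3 had the opposite sign by that count. Changes of sign in differences called in neither setting were not counted. All 3 opposite signs are values of another probe of the gene than the reported one. Probes of called genes often disagreed beyond these named genes. In the 3 comparisons, 341, 913 and 691 called genes had another tested probe. At least 1 such probe was not called in 239, 546 and 413 of these genes. One of opposite sign was found in 50, 101 and 65, and it was called in 2, 6 and 1. Man1b1 between MI and intact heart was -2.51 and became 0.18 with a detection p under 0.01 on all arrays, and -0.01 without intact heart replicate 1. Pkm between intact heart and peritoneal cavity was -1.04 and became 0.90 with every probe on its own. In that setting the probe with the smallest p stood for each named gene, so a call could hardly be lost, and 0 were. A gene was also counted there if any of its probes was called. That setting is therefore no check of these calls and counts. Slc16a3 between MI and intact heart was 1.87 and ranged from -0.28 to 2.15 with each array left out in turn, lowest without MI heart replicate 1, where the reported probe itself gave 1.55 (adjusted p = 0.026). Of the 44 list calls, 29 were called under all alternatives that kept the preset correlation and gave a value. For 7 of these 29 the detection p under 0.01 on all arrays gave none. The signal over background limits the genes near it, for which a fold is only a lower bound, and the number of arrays limits precision.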

Other observations

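No test in this part was chosen after its result was seen.

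Of 5 further gene lists tested between MI and intact heart in this paragraph, 3 were called with the preset correlation. Lysosome genes were higher in the MI heart for 3 of 12 members, lower for 0 and not called for 9, with 3 higher adjusted over the list alone (adjusted p = 0.00142; adjusted p = 0.187 with an estimated correlation), and between MI heart and peritoneal cavity for 5, 0 and 7, with 6 higher adjusted over the list alone (adjusted p = 0.00077; adjusted p = 0.187 with an estimated correlation). Between MI and intact heart, the called members Ctsd and Ctsl lost their calls under 3 and 6 of 17 alternatives, and Gpnmb under 0. Lgmn, a lysosomal protease, was higher in the MI heart than in the peritoneal cavity by 1.25 ± 0.15 (adjusted p = 0.000565). Lipid and cholesterol handling genes were higher in the MI than the intact heart for 3 of 11 members, lower for 0 and not called for 8, with 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.00179; adjusted p = 0.187 with an estimated correlation). The lipid call was lost with a detection p under 0.01 on all arrays (adjusted p = 0.122). The cholesterol-sensing receptor gene Nr1h3 rose by 2.13 ± 0.28 (adjusted p = 0.00297; adjusted p = 0.0698 with no filter). Complement genes were higher for 1 of 10 members, lower for 0 and not called for 9, with 2 higher adjusted over the list alone (adjusted p = 0.0247; adjusted p = 0.205 with an estimated correlation), and Cfb, complement factor B, rose by 1.98 ± 0.18 (adjusted p = 0.000573). The complement call was lost without intact heart replicate 2 (adjusted p = 0.0816), without MI heart replicate 1 (adjusted p = 0.0543) and with a detection p under 0.01 on all arrays (adjusted p = 0.0933). Apoptotic cell uptake genes were higher for 1 of 14 members, lower for 3 and not called for 10, with 1 higher and 5 lower adjusted over the list alone and no call for the list (adjusted p = 0.519; adjusted p = 0.605 with an estimated correlation), and the list median (0.03) and mean (-0.08) differed in sign. Cell cycle genes had 0 of 16 members called by limma, also adjusted over the list alone, and 2 at an unadjusted p under 0.05 (adjusted p = 0.766; adjusted p = 0.877 with an estimated correlation).

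Among reference genes, 2 of 9 were higher in the MI than the intact heart, 0 lower and 7 not called, the same adjusted over the list alone, with no call for the list (adjusted p = 0.196; adjusted p = 0.36 with an estimated correlation). Both belong to glycolysis: Pgk1 (1.94 ± 0.28, adjusted p = 0.00476; adjusted p = 0.0877 without MI heart replicate 1 and 0.0842 with no filter) and Gapdh (0.85 ± 0.22, adjusted p = 0.0468), whose adjusted p lay between 0.116 and 0.291 without intact heart replicate 2, either MI heart array or either peritoneal array, and between 0.063 and 0.207 under 5 other alternatives. General macrophage genes were higher in the MI heart than in the peritoneal cavity for 4 of 13 members, lower for 1 and not called for 8, with 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.0105; adjusted p = 0.205 with an estimated correlation), a call lost without MI heart replicate 2 (adjusted p = 0.0838) and with a detection p under 0.01 on all arrays (adjusted p = 0.0614). Cd14, a receptor for bacterial lipopolysaccharide, was higher there by 1.65 ± 0.17 (adjusted p = 0.000223) and Lyz2, lysozyme, lower (-0.88 ± 0.17, adjusted p = 0.00842). Of 3 endothelial markers, 1 was higher in the MI than the intact heart, 0 lower and 2 not called, with 2 higher adjusted over the list alone (adjusted p = 0.0229; adjusted p = 0.223 with an estimated correlation). Rgcc, that marker, rose by 1.45 ± 0.20 (adjusted p = 0.00351), and the list call was lost without intact heart replicate 1 (adjusted p = 0.0941), intact heart replicate 2 (adjusted p = 0.201), MI heart replicate 1 (adjusted p = 0.0586) or peritoneal replicate 2 (adjusted p = 0.0897), with median scaling (adjusted p = 0.0643) and with no filter (adjusted p = 0.127).

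Markers of other leukocytes gave few calls. Of 4 neutrophil markers tested, 1 was higher in the MI than the intact heart, 0 lower and 3 not called, with 2 higher adjusted over the list alone and no call for the list (adjusted p = 0.241; adjusted p = 0.4 with an estimated correlation). Among 4 dendritic cell markers, 0 were higher, 1 lower and 3 not called, with 2 lower adjusted over the list alone (adjusted p = 0.318; adjusted p = 0.461 with an estimated correlation). Siglech, a lectin of plasmacytoid dendritic cells, was the lower one (-1.25 ± 0.16, adjusted p = 0.00284; adjusted p = 0.0521 without MI heart replicate 2). B cell markers had 0 of 4 members called by limma, also adjusted over the list alone, and 1 at an unadjusted p under 0.05 (adjusted p = 0.991; adjusted p = 0.992 with an estimated correlation). Of 6 smooth muscle and pericyte markers, 0 were higher in the MI than the intact heart, 1 lower and 5 not called, with 2 lower adjusted over the list alone (adjusted p = 0.0687; adjusted p = 0.275 with an estimated correlation). The lists of T and NK cells (2 members tested), mast cells and eosinophils (1), mesothelium (2) and red blood cells (1) had fewer than 3 tested members and no list test. Of the 2 T and NK cell markers, 1 was called higher in the MI than the intact heart, and 1 higher than in the peritoneal cavity.

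Against the peritoneal cavity, lysosome genes of the intact heart were higher for 3 of 12 members, lower for 2 and not called for 7, the same adjusted over the list alone (adjusted p = 0.302; adjusted p = 0.461 with an estimated correlation). Lipid handling genes were lower there for 3 of 11 members, higher for 0 and not called for 8, the same adjusted over the list alone (adjusted p = 0.188; adjusted p = 0.36 with an estimated correlation), and Lpl, lipoprotein lipase, was lower in the intact heart (-1.15 ± 0.17, adjusted p = 0.00151) and in the MI heart (-1.60 ± 0.17, adjusted p = 0.000287). Apoptotic cell uptake genes were higher in the intact heart for 6 of 14 members, lower for 4 and not called for 4, the same adjusted over the list alone, with no call for the list (adjusted p = 0.318; adjusted p = 0.473 with an estimated correlation). Axl, a receptor for apoptotic cells, was higher in the intact heart (2.73 ± 0.21, adjusted p = 3.45e-05). Cell cycle genes were higher in the MI heart than in the peritoneal cavity for 1 of 16 members, lower for 0 and not called for 15, the same adjusted over the list alone (adjusted p = 0.019; adjusted p = 0.36 with an estimated correlation), a call lost without MI heart replicate 2 (adjusted p = 0.117), without peritoneal replicate 1 (adjusted p = 0.119) and with a detection p under 0.01 on all arrays (adjusted p = 0.0814).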
